A study of Gallus gallus with 9 samples.

How the data were processed

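RNA from the livers of 9 ROSS308 broilers was measured on a 1-colour Affymetrix chicken expression array, with 1 array per bird. Per the labels' protocols, RNA was extracted with Trizol, cleaned on a column, and 7 ug were turned into biotin-labelled cRNA. The labels number the samples of each group as biological replicates and name no batch, scan date, pairing or sex. The series design states that 1 further control sample failed the quality requirements and was left out before deposit. The comparison therefore has 4 control birds and 5 Se-yeast birds.

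The deposited values are probe set intensities on a linear scale. Per the submitters' processing notes they come from MAS5, the Affymetrix algorithm that summarises the probes of a probe set into a signal and scales each array; its version is not given in the sources used here. On every array the mean of the values between the 2nd and 98th percentiles was 499.9, which is the trace of that scaling. The values had not been log transformed, and no detection calls were used here, so a low signal could not be called present or absent. Scaling to a common mean makes each change relative to the rest of the array, and it cannot show a change in the total RNA of a liver cell. MAS5 signals near background vary strongly on a log scale. For that reason 16 was added to each signal before log2 was taken, which pulls the fold changes of dim probe sets towards 0. Arrays have no read depth. The number of arrays limits the precision.

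The table held 38535 probe sets, of which 96 array controls were kept out of the tests. Of the rest, 27168 had 1 gene symbol in the platform annotation, 177 had several and 11094 had none here; genes were named only from the first kind, which covered 13009 distinct symbols. The gene identifiers of 26853 of these probe sets matched the RefSeq gene table of the GRCg7b assembly. That table was used only for chromosome membership (Z, W or a numbered chromosome), and no coordinates are given. Probe set identifiers ending in _s_at or _x_at mark probes that can also read related transcripts, so a value from such a probe set need not belong to the named gene alone.

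The design, the gene lists, the rule for named genes and all alternatives but 1 were written before the data were examined. Probe sets were tested when their mean log2(signal + 16) over the 9 arrays was at or above the 40th percentile (6.33, a signal of 64.7), which left 23063. Each was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), comparing Se-yeast with control without covariates. The tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method over all 23063, with a threshold of 0.05. Fold changes are on the log2(signal + 16) scale, given as Se-yeast minus control, and errors of means are SDs between birds. Intervals have 95% confidence.

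A total of 32 gene lists was fixed from textbook knowledge of liver, selenium and poultry physiology, and 31 had at least 4 measured genes. Each gene was represented by its brightest tested probe set over all 9 arrays, giving 10382 genes. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 31 lists. Camera with an estimated correlation and fry (a rotation test of whether a list's genes move, on balance, one way) were run as alternatives. Array measures and list levels per bird were compared by exact permutation over all 126 ways to part 9 birds into 4 and 5. The exact p-values of list levels were not adjusted over the 31 lists. The smallest p that this design allows is 0.00794.

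The genes named are the 12 probe sets with the largest rise and the 12 with the largest fall among those past the threshold with 1 symbol, filled up to 12 by the smallest unadjusted p where fewer passed. Every measured selenoprotein gene and up to 4 members of each other list with the smallest p are also open to naming. Probe sets outside that rule are said to have been chosen after their values were seen.

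The analysis was tested on data simulated with the means and spread of the same 23063 probe sets, 200 of them changed in each of 5 runs. It found 2.4% of those changed by 0.5 on the log2 scale, 51.4% of those changed by 1 and 96.8% of those changed by 2, with a mean of 5 false calls a run and no wrong sign. These shares belong to 200 changed probe sets. Where fewer change, the Benjamini-Hochberg adjustment is stricter and a smaller share would be found. A list shifted by 0.4 was found in 5 of 5 runs, and no other list was called. The simulated noise was independent between probe sets, whereas genes of real lists were correlated, at an estimated 0.51 for ribosomal proteins. The runs therefore do not give the rate of false list calls in the real data. With 4 and 5 birds, single genes that change by less than about 2-fold are therefore mostly missed.

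Alternatives covered a pseudocount of 1 or 64, no filter or one at the 60th percentile, quantile normalisation, centring on the array median, 2 other variance models, array weights, ordinary statistics, other thresholds, the replicate number as a block, each bird left out in turn, a W-chromosome marker as a covariate, the mean of a gene's probe sets, and the other list tests. A second W-chromosome probe set was added as a covariate after the data were seen. Outside the alternative with the replicate block, the replicate numbers were not used to pair birds. With the group means subtracted, control and Se-yeast birds of the same number correlated at only -0.11 to 0.04. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.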

Results

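Liver gene expression was compared between broilers, chickens bred for meat, that ate a standard diet from hatching to slaughter and broilers that ate the same diet with selenized yeast. Selenized yeast carries selenium mainly as selenomethionine, and here it added 0.5 mg of selenium per kg of diet over 35 days. The control group had 4 birds and the Se-yeast group had 5. The median signal was 107 on average over the control arrays and 113 over the Se-yeast arrays, with single arrays from 100.5 to 125 (exact permutation p = 0.429, two-sided). The 3′ to 5′ ratio of the GAPDH control probes, a measure of RNA integrity, was 0.806 ± 0.0295 and 0.805 ± 0.0467 in the same order (exact permutation p = 0.976). None of the 6 array measures differed after adjustment, the smallest being the mean correlation with the other arrays, at 0.953 ± 0.00253 in control and 0.948 ± 0.00306 in Se-yeast birds (exact permutation p = 0.0397, adjusted p = 0.238).

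The diets were compared to find which liver transcripts respond to the supplement. Genes of selenoproteins, the proteins that carry selenium as selenocysteine, made up all of the named increases that passed the threshold. GPX3, the secreted glutathione peroxidase of plasma, rose 3.06-fold, from a signal of 15623 ± 3488 (SD, n = 4) to 47134 ± 4115 (SD, n = 5; adjusted p = 0.00159). GPX1, the cytosolic glutathione peroxidase that removes hydrogen peroxide, rose 2.24-fold, from 5436 ± 454 to 12191 ± 1044 (adjusted p = 0.00174). SELENOH, a nuclear selenoprotein, rose from a signal of 48.6 ± 34.3, which lay below the filter level, to 376 ± 44.7 (adjusted p = 0.00657). Its fold depends on the constant added to dim signals and was 2.75 on the log2 scale, between 2.01 and 3.19 under the alternatives. SELENOP1, which encodes the selenium transport protein secreted by the liver, rose 2.14-fold on the probe set that passed, from 9252 ± 1291 to 19963 ± 3884 (adjusted p = 0.0415). That probe set can also read related transcripts. In each of these 4 genes the lowest Se-yeast bird lay above the highest control bird. Chance alone parts the groups, in either direction, for 1.59% of probe sets, and these 4 were picked by their p in the same birds.

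**Figure D1:**
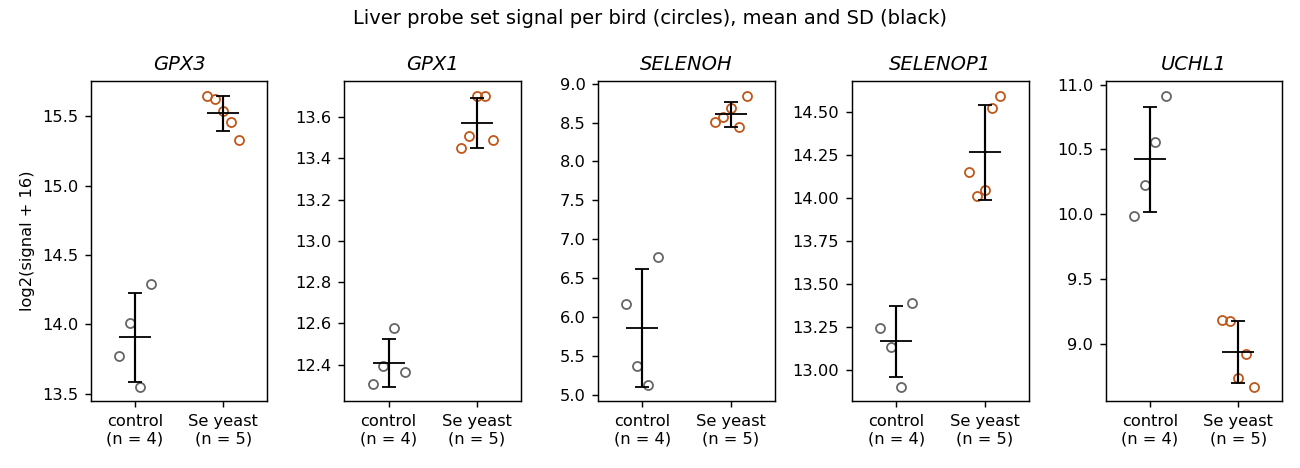
Log2(signal + 16) of the 5 probe sets with 1 gene symbol that passed the threshold, on the vertical axis of each panel (each with its own range, not starting at 0), for 4 control birds (grey circles) and 5 Se-yeast birds (orange circles); the black bar is the mean and the whiskers are the SD. GPX3, GPX1, SELENOH and SELENOP1 were higher in all 5 Se-yeast birds than in any control bird, and UCHL1 was lower in all 5.

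UCHL1, a ubiquitin hydrolase best known from neurons, fell by 1.49 on the log2 scale, from a signal of 1397 ± 401 (SD, n = 4) to 479 ± 82.1 (SD, n = 5; adjusted p = 0.0337), and no Se-yeast bird reached the lowest control bird. The gene's other probe sets lay below the signal filter, at 0.83 and -0.69, so the call rests on 1 probe set. The sixth probe set past the threshold carries 2 gene symbols and is left unnamed; it fell by 1.75 on the log2 scale, from 9620.1 ± 2059 to 2977 ± 1168 (adjusted p = 0.0495). In all, 6 of 23063 probe sets passed, 4 higher and 2 lower. At an unadjusted p under 0.05 there were 1078, where chance alone gives 1153. GPX3 and GPX1 stayed past the threshold under each of the 21 alternatives in which single genes were followed. Ordinary statistics were not among these, and with them GPX3 and GPX1 did not both pass. The count of probe sets was 3 without control replicate 3 and without Se-yeast replicates 1, 3 or 4. Over the alternatives the log2 fold changes kept their size, at 1.01 to 1.23 for SELENOP1, -1.63 to -1.32 for UCHL1 and -1.94 to -1.59 for the unnamed probe set. Their adjusted p did not stay under 0.05. SELENOP1 lost its call when any bird but Se-yeast replicate 2 was left out, UCHL1 when any bird but control replicate 1 or Se-yeast replicate 2 was left out, and the unnamed probe set when any bird but Se-yeast replicate 5 was left out. With the first W-chromosome marker as a covariate these probe sets and SELENOH (adjusted p = 0.0529) lost their calls. SELENOH also lost its call with the replicate number as a block (adjusted p = 0.142, log2 fold change 2.69). It passed under 18 of 20 alternatives, the second W-chromosome covariate among them.

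Across the selenoprotein list, 23 of 25 genes were measured. Of these, 18 had a positive and 5 a negative fold change. With centring on the array median TXNRD3 and SELENOT turned negative, at -0.03 and -0.04. The median change was 0.21 on the log2 scale and the mean 0.43, and the list was higher in Se-yeast livers (camera adjusted p = 8.3e-10; adjusted p = 0.0225 with an estimated correlation; fry adjusted p = 0.00365). The mean log2 level of the list was 11.67 ± 0.11 (SD, n = 4) in control and 12.10 ± 0.09 (SD, n = 5) in Se-yeast birds, with no overlap between the groups (exact permutation p = 0.00794, the smallest possible). The median over all 23 genes, 0.21, had an exact permutation p of 0.0635. Several other splits of the birds gave a median at least as far from 0, among them one of 0.23 in size. Without Se-yeast replicate 1 the median was 0.28 (exact permutation p = 0.0286), and without control replicate 2 it was 0.32. Over the 20 genes other than GPX3, GPX1 and SELENOH it was 0.18 (exact permutation p = 0.0159).

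Counted on the brightest probe set of each gene, 3 selenoprotein genes passed over all probe sets and 8 passed adjusted over the list alone, all of them higher. Beyond GPX3, GPX1 and SELENOH, these were PRXL2A, a peroxiredoxin-like protein, at 0.83 on the log2 scale, GPX4, the peroxidase that reduces lipid hydroperoxides, at 0.58, DIO1, the hepatic deiodinase that activates thyroid hormone, at 0.57, SELENOP1 at 0.52 and SELENOP2 at 0.44. None of these 5 values passed over all probe sets. The 4 bright probe sets of SELENOP1 gave 1.10, 1.05, 0.55 and 0.52, so the size of its change depended on the probe set, and the brightest gave the least. All of these but the brightest can also read related transcripts. Genes that passed neither way included SELENON at 0.69, DIO3 at 0.51, TXNRD2 at 0.34, SELENOW at 0.21 and SELENOO at 0.20. SELENOM and SELENOF each stood at 0.17, SELENOI at 0.10, and TXNRD3 and SELENOT each at 0.02. The 5 negative values were those of MSRB1 (-0.10), SELENOK (-0.17), DIO2 (-0.22), SELENOS (-0.26) and GPX2 (-0.33), all within the spread between birds. TXNRD1 lay below the signal filter, and SEPHS2 was not analysed here.

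**Figure D2:**
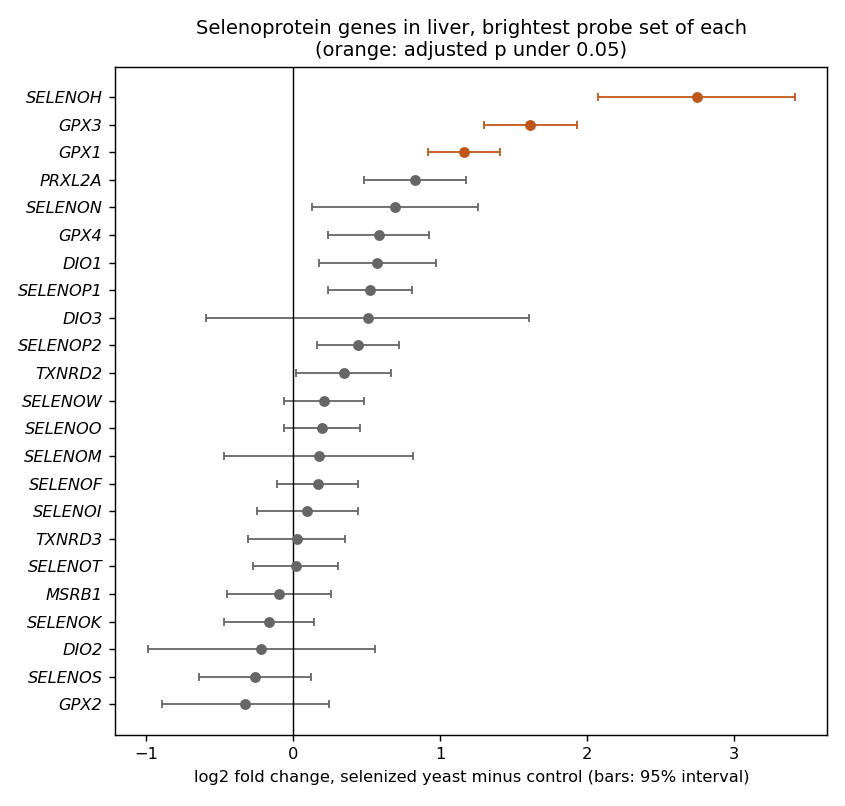
Log2 fold change between 5 Se-yeast and 4 control birds on the horizontal axis for the 23 measured selenoprotein genes, each on its brightest probe set; bars are 95% intervals and orange marks an adjusted p under 0.05 over all probe sets. SELENOH, GPX3 and GPX1 lie furthest to the right, at 2.75, 1.61 and 1.16, and GPX2 lies furthest to the left at -0.33.

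Genes that make selenocysteine and handle selenium were compared as a separate list. The 13 measured genes of selenocysteine synthesis and selenium handling, 7 higher and 6 lower, had a median of 0.00 and a mean of -0.05 (camera adjusted p = 0.292). The members with the smallest p were SEPSECS, the enzyme that makes selenocysteine on its tRNA, at -0.33, and SELENBP1 at 0.29. Next came SCLY, the lyase that frees selenium from selenocysteine, at -0.26, and SEPHS1 at -0.29. SEPSECS was lower in every Se-yeast bird than in any control bird but did not pass (adjusted p = 0.999). Such a parting of the groups, in either direction, arises by chance in 1.59% of probe sets. Antioxidant and glutathione genes outside the selenoproteins had a median of -0.05 over 36 genes (camera adjusted p = 0.139). Their members with the smallest p were the glutathione transferases GSTA3 at -1.05 and GSTA4 at -0.42, the ferritin subunit FTH1 at 0.27 and heme oxygenase HMOX1 at 0.36, and none passed. Genes of the thyroid and growth hormone axis, which share DIO1 and DIO3 with the selenoprotein list, had a median of 0.12 over 24 genes (camera adjusted p = 0.228).

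Other genes high in the ranking did not pass. C8orf22, an uncharacterised gene, was closest, 1.98-fold higher at signals of 14084 ± 3340 (SD, n = 4) and 27537 ± 3015 (SD, n = 5; adjusted p = 0.0750). It passed with quantile normalisation and without control replicate 4. APOA5, an apolipoprotein of triglyceride metabolism, was 1.93-fold higher (adjusted p = 0.163) and passed without Se-yeast replicate 2. SLC25A30, a mitochondrial carrier, was 1.99-fold higher, the growth factor HGF 2.36-fold and the acute-phase protein ORM1 1.67-fold, at adjusted p from 0.371 to 0.999. A dim probe set of the splicing regulator MBNL1 stood at 1.61 (adjusted p = 0.739) and passed without Se-yeast replicate 2, but the bright ones for the gene stood at 0.02 and 0.14. Likewise a dim probe set of VWA5B1 stood at 1.74 (adjusted p = 0.370) and a brighter one at 0.34. On the lower side stood the defensin AvBD13 at -1.12, the retromer subunit VPS26B at -1.87 and the adaptor AZI2 at -0.73. The proprotein convertase PCSK7 stood at -1.62 on its dimmest probe set and at -0.18 and -0.20 on brighter ones, and the kinase regulator MOB1B at -0.75 on one probe set and -0.18 on the other. The smaller values were those of the ubiquitin-like modifier UFM1 at -0.51 and -0.54 on its probe sets, TKTL1 at -0.43, ENAH at -0.54 and -0.39, and MYLIP, a ubiquitin ligase of lipoprotein receptors, at -0.52. None of these passed, although VPS26B did without control replicate 4. A probe set of CYP2C23b, a cytochrome P450, stood at -5.31 (adjusted p = 0.371), because its signal was high in 3 control birds and low in the fourth and in all 5 Se-yeast birds. It passed without control replicate 2, and a brighter probe set of the gene stood at 0.46.

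Genes of the acute phase response and of hepatocyte identity had more positive than negative fold changes. In the acute phase and complement list 26 of 32 measured genes were higher and 6 lower, with a median of 0.22 (camera adjusted p = 2.91e-07; adjusted p = 0.436 with an estimated correlation). ORM1 stood at 0.74, complement C3 at 0.40, C4 at 0.38 and the transcription factor STAT3 at 0.37. Only ORM1 passed adjusted over the list alone, and none over all probe sets. The mean level of the list was 13.49 ± 0.08 in control and 13.70 ± 0.14 in Se-yeast birds (exact permutation p = 0.0476). The mean change of the list was 0.20, and 0.12 with quantile normalisation. Hepatocyte markers, which share 2 genes with that list, were higher for 14 of 19 genes, with a median of 0.15 (camera adjusted p = 0.00598; adjusted p = 0.437 with an estimated correlation), among them AHSG at 0.38, TTR at 0.39, ALB at 0.36 and F9 at 0.32. The hepatocyte call was lost without control replicate 2 or Se-yeast replicate 1, with either W-chromosome covariate and with quantile normalisation, which brought its mean from 0.14 to 0.02. Over all alternatives that mean lay between 0.02 and 0.17, and without Se-yeast replicate 1 it was 0.08. For the mean level of the hepatocyte list per bird, the exact permutation p was 0.111.

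Markers of macrophages and genes of the interferon response also lay mostly on the higher side. Markers of macrophages and Kupffer cells were higher for 20 of 21 genes, with a median of 0.17 (camera adjusted p = 8.76e-04; adjusted p = 0.436 with an estimated correlation), led by the growth factor receptor CSF1R at 0.36 and the invariant chain CD74 at 0.32. Their mean level was 11.81 ± 0.10 (SD, n = 4) in control and 11.97 ± 0.07 (SD, n = 5) in Se-yeast birds (exact permutation p = 0.00794, not adjusted over the lists). The groups were barely apart, with control replicate 3 at 11.9066 and Se-yeast replicate 3 at 11.9073. Interferon response genes were higher for 22 of 32 genes, with a median of 0.15 (camera adjusted p = 0.0191; adjusted p = 0.437 with an estimated correlation), with ZNFX1 at 0.73, B2M at 0.34, IFI6 at 0.56 and IFIT5 at 0.54. The mean level of the interferon list had an exact permutation p of 0.230. The interferon call was lost without control replicates 1 or 3, without Se-yeast replicates 1 or 3 and with either W-chromosome covariate, and the macrophage call with the first of these covariates. The mean change lay between 0.10 and 0.19 over the alternatives for macrophage markers and between 0.11 and 0.25 (without control replicate 2) for the interferon list. No member of either list passed, over all probe sets or adjusted over the list alone.

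**Figure D3:**
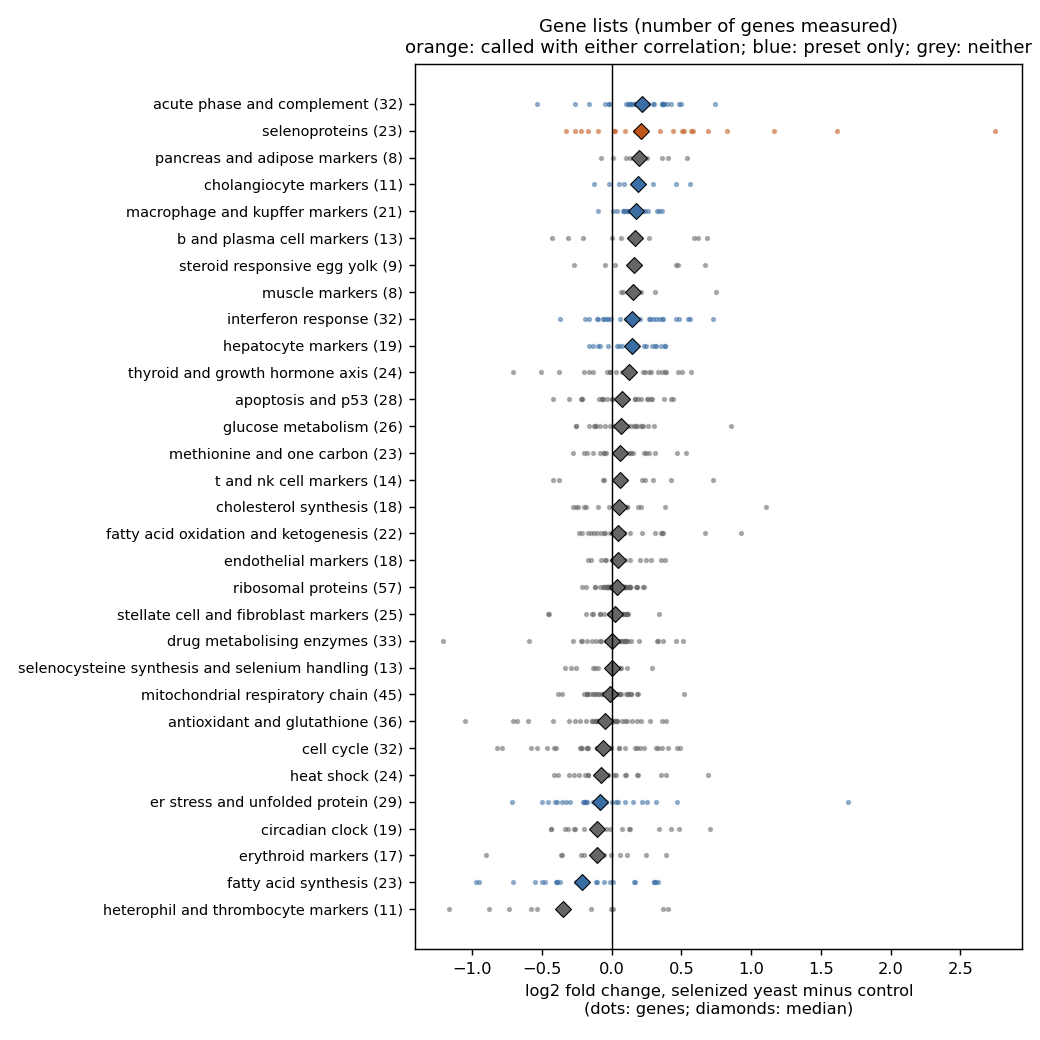
Log2 fold change between 5 Se-yeast and 4 control birds on the horizontal axis for each measured gene (dots) of the 31 tested lists, with the list median as a diamond and the number of genes in brackets. The 8 coloured lists passed camera with the preset correlation, and of these the selenoproteins, in orange, passed with the estimated correlation too; their dots reach 2.75, further than those of any other list.

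Fatty acid synthesis genes lay mostly on the lower side: 16 of 23 were lower, with a median of -0.21 (camera adjusted p = 0.0482; adjusted p = 0.437 with an estimated correlation). The lipid transfer protein gene MTTP stood at -0.40, the adipogenic receptor PPARG at -0.50, the acyltransferase GPAM at -0.47 and malic enzyme ME1 at -0.71. ME1 was low only in Se-yeast replicates 4 and 5, at 12.41 and 12.67 on the log2 scale. The other Se-yeast birds, at 14.05 to 14.47, lay within the control range of 13.93 to 14.70. The call passed under 12 of 24 alternatives and was lost without control replicates 1 or 4 and without Se-yeast replicates 3, 4 or 5. The mean change of the list, -0.21, lay between -0.44 (with a W-chromosome covariate, adjusted p = 2.42e-06) and -0.12 (without Se-yeast replicate 5), and was -0.14 without control replicate 4 or Se-yeast replicate 4. The mean level of the list varied more within the Se-yeast group (12.29 ± 0.34, SD, n = 5) than the distance to control (12.50 ± 0.17, SD, n = 4; exact permutation p = 0.302). Cholesterol synthesis genes had a median of 0.05 (camera adjusted p = 0.727), although HMGCS1, which commits acetyl units to that pathway, stood at 1.10; its signal in Se-yeast birds was 15142 ± 9749 (SD, n = 5) and overlapped that of control birds. Fatty acid oxidation and ketogenesis genes had a median of 0.05 (camera adjusted p = 0.228), with ECI2 at 0.37 and the coactivator PPARGC1A at 0.67.

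Genes of endoplasmic reticulum stress and the unfolded protein response were lower for 19 of 29, with a median of -0.09 and a mean of -0.05 (camera adjusted p = 0.0250; adjusted p = 0.437 with an estimated correlation). The chaperones CANX at -0.35 and HSP90B1 at -0.39 and the folding factor CRELD2 at -0.72 lay on that side, and CHAC1, a glutathione-degrading enzyme, lay on the other at 1.69. No member passed, and the mean lay between -0.12 (without control replicate 3) and 0.02 (without control replicate 1); the call was also lost without control replicate 2, without Se-yeast replicates 2 or 5, with variances fitted without a trend, with the replicate block and with the first W-chromosome covariate. For the mean level of the endoplasmic reticulum stress list per bird, the exact permutation p was 0.651. Heat shock genes had a median of -0.08 (camera adjusted p = 0.0843), with HSP90AA1 at -0.38.

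The other pathway lists did not pass with the preset or the estimated correlation. Their medians were 0.07 for glucose metabolism, 0.06 for methionine and one-carbon metabolism (MAT1A, which makes S-adenosylmethionine, at 0.31), 0.08 for apoptosis and p53 targets, -0.06 for the cell cycle (MCM3 at -0.82 and BUB1 at -0.78), -0.10 for the circadian clock, 0.00 for drug-metabolising enzymes, 0.16 for oestrogen-responsive egg yolk genes, -0.01 for the mitochondrial respiratory chain and 0.04 for ribosomal proteins, at camera adjusted p from 0.164 to 0.972. No gene of these lists passed.

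Markers of other cell types that a liver sample can hold were compared in the same way. Cholangiocyte markers were higher for 9 of 11 genes, with a median of 0.19 (camera adjusted p = 0.0482; adjusted p = 0.437 with an estimated correlation), with CLDN3 at 0.46 and EPCAM at 0.30. This call passed under only 6 of 24 alternatives and held in the absence of a bird only for control replicate 4 and Se-yeast replicate 4, with a mean between 0.10 and 0.25 (0.12 without control replicate 1). Per bird, the mean level of the cholangiocyte list had an exact permutation p of 0.103. Muscle markers had a median of 0.15 (camera adjusted p = 0.0805), pancreas and adipose markers 0.19 (0.292) and B and plasma cell markers 0.17 (0.426). The medians were 0.06 for T and NK cell markers (0.379), 0.05 for endothelial markers (0.292) and 0.02 for stellate cell and fibroblast markers, with a mean of -0.02 (0.972). Erythroid markers had a median of -0.10 (0.320) and heterophil and thrombocyte markers -0.35 (0.228), with a wide spread of the mean level between birds, 9.21 ± 0.43 (SD, n = 4) in control and 8.88 ± 0.63 (SD, n = 5) in Se-yeast birds (exact permutation p = 0.389).

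HINTW, a gene of the female W chromosome, had a signal of 16428 in Se-yeast replicate 1 and at most 19.5 in the other 8 birds. The median distance of 462 Z-linked probe sets from the mean of the other birds, less that of 10000 autosomal probe sets, was -0.46 on the log2 scale in that bird. In the other birds it lay between 0.01 and 0.15. SELENOP1 is annotated on the Z chromosome, and the other named genes past the threshold are annotated on autosomes. Without this bird 3 probe sets and 5 gene lists passed, against 6 and 8 with it, and the selenoprotein median was 0.28 against 0.21.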

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

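The tests of chance splits, of bright probe sets and of Se-yeast replicate 1 alone were set before the selenoprotein result was seen. Selenoprotein genes were higher in Se-yeast livers, and the diet is one explanation. Another is that bright probe sets were scaled up on the Se-yeast arrays; of 10000 random lists matched on brightness, 0% had a median as high as 0.21, which speaks against it. It could also be that Se-yeast replicate 1 alone carried the result; without it the median was 0.28 (exact permutation p = 0.0286), which speaks against that too. Of 100 splits of the birds, the real one included, 2 gave at least the 6 probe sets seen, so chance is an unlikely source of all of them, but the split of control replicates 1 and 4 and Se-yeast replicates 4 and 5 against the other birds gave 68 and points to structure among the samples that the diets do not describe. For the gene lists, 22 of 100 splits gave as many as the 8 seen, so that number could have arisen by chance, and the 7 lists other than the selenoproteins rest on the preset correlation. With an estimated correlation the selenoproteins had an adjusted p of 0.0225, and 2 of the 100 splits, the real one included, gave some list at or below that value, the other at 0.0193; 5 of the 99 other splits gave some list under 0.05.

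The tests of sex and of weak hybridisation were chosen after the HINTW value was seen. HINTW stood at 14.01 on the log2 scale in Se-yeast replicate 1 and between 4.48 and 5.15 in the other Se-yeast birds; its signal was at most 19.5 in all 8 other birds. One explanation is that this bird was female and the others male; its Z-linked median relative to autosomal probe sets was -0.46, below the lowest other bird at 0.01, as a female with a single Z chromosome would show. Another is a weaker hybridisation of its sample. Z-linked probe sets lay below the mean of the other birds more often than autosomal ones by 34.7 percentage points, which speaks against this as the source of the pattern. In every other bird they lay below it less often than autosomal ones, by at most 17.4 points. The hybridisation controls on this bird's array stood at 2.33-fold the mean of the other 8, so a weaker sample on that array was not ruled out. With 1 bird of this HINTW pattern, in 1 group, sex and diet are partly mixed. Without this bird the Z-linked SELENOP1 stood at 1.13, against 1.10 with it.

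The tests of probe sets that switch between birds were chosen after these values were seen. In 8 probe sets the birds fell into a high and a low set at least 4 log2 units apart, and 0 of them separated the diets; among them CYP2C23b stood at -5.31. Sequence differences between birds under the probes could cause this, and for 100% of the 5 with a second bright probe set for the gene, that one differed by less than 0.5 of the gap, but 4 of these 5 can also read related genes, so the test does not decide. A fall of the whole CYP2C23b transcript with the diet would lower its brighter probe set too, which stood at 0.46 (95% interval -0.11 to 1.04), but that probe set can read related genes and the matter stays open.

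Single birds that stood apart were screened in 166 groups, and 7 were marked where 8.3 would be by chance. Chance flags about 1 in 20 groups, so none of these values is evidence of a fault on its own. Each bird was compared only with the others of its own diet group, and the ranges given are those of that group. MBNL1 stood at 6.70 on the log2 scale in Se-yeast replicate 2, with the others of its group at 8.45 to 8.67. CYP2C23b stood at 7.68 in control replicate 2, with the others of its group at 13.30 to 14.22. GPX2 stood at 7.94 in Se-yeast replicate 2, with the others of its group at 6.82 to 7.14. DIO3 stood at 7.03 in Se-yeast replicate 5, with the others of its group at 8.41 to 8.86. The hybridisation controls stood at 13.68 in Se-yeast replicate 1, with the others of its group at 12.31 to 12.67. The actin 3′ to 5′ ratio was 2.61 in control replicate 1, with the others of its group at 1.89 to 1.95, and it reached 2.66 in the Se-yeast group. HINTW stood at 14.01 in Se-yeast replicate 1.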

How the results depend on the processing

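GPX3 and GPX1 kept their direction and their side of the threshold under all 21 alternatives in which single genes were followed. Ordinary statistics were not among these, and with them GPX3 and GPX1 did not both pass. The selenoprotein list kept its direction and its side of the threshold under all of its own, with a median from 0.15 to 0.32 over the birds left out. The count of probe sets, 6, was changed by several choices. It was 3 with variances fitted without a trend, 3 with the replicate block, 2 with the W-chromosome marker as a covariate, 3 with the HINTW covariate added after the data were seen, 1 with ordinary statistics, and 514 at an unadjusted p under 0.05 with a 1.5-fold change. It was 3 without control replicate 3 and 7 without Se-yeast replicate 2. The cause was not tested. Adjusted p ranged from 0.0281 to 0.329 for SELENOP1 and from 0.0119 to 0.413 for UCHL1. The count of gene lists, 8, was 5 without a trend, 5 with either covariate, 1 with an estimated correlation, 1 with fry, 4 without control replicate 1 and 9 without control replicate 4. The cause was not tested.

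Small changes of single genes turned sign. TXNRD3 stood at -0.0346 with median centring and at -0.0336 with the replicate block, and from -0.0336 (without Se-yeast replicate 5) to 0.110 (without Se-yeast replicate 4). SELENOT stood at -0.0428 with median centring, and from -0.0803 (without Se-yeast replicate 2) to 0.0739 (without Se-yeast replicate 4). DIO2 stood at 0.0349 with the W-chromosome covariate, and from -0.47 (without Se-yeast replicate 4) to 0.0729 (without Se-yeast replicate 3). SELENOI stood at -0.0743 with the W-chromosome covariate. DIO3 ranged from -0.0842 (without control replicate 3) to 0.85 (without control replicate 2), and SELENOM from -0.0151 (without Se-yeast replicate 2) to 0.41 (without Se-yeast replicate 5). The mean of the endoplasmic reticulum stress list ranged from -0.12 (without control replicate 3) to 0.0163 (without control replicate 1). The cause was not tested.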

Other observations

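Lipid synthesis genes differed between birds of the same diet. The mean log2 level of the fatty acid synthesis list was 12.64 in Se-yeast replicates 1 and 2, 12.22 in replicate 3 and 11.93 in replicate 5, and in control birds it lay between 12.29 and 12.71. The cholesterol synthesis list ran from 11.38 to 12.20 in Se-yeast birds and from 11.64 to 11.84 in control birds. After these values were seen, the nutritional state of single birds at slaughter was considered, which could set synthesis against oxidation. Across the 9 birds the levels of the synthesis and oxidation lists correlated at -0.24 (exact permutation p = 0.545; Spearman -0.22), and at 0.45 without Se-yeast replicates 4 and 5, so the question stays open.

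A pair of the 3 probe sets without a gene symbol that are named for coding regions of the same sequence were chosen after their values were seen. They had signals of 8374 and 1007 in Se-yeast replicate 5, and the first also had 2261 in control replicate 4; all other arrays were at or below 134. The remaining probe set of that sequence was at or below 86.6 on every array, with 37.7 in Se-yeast replicate 5 and 22.1 in control replicate 4. Of 683 probe sets named in that way, 2 reached 1000 on any array, and the median was 15.5. What they measure was not determined.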
